A study of Rattus norvegicus with 6 samples.

How the data were processed

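RNA of cultured rat hippocampal astrocytes and hippocampal neurons was measured by sequencing of total RNA after ribosomal RNA depletion with a stranded kit, per the labels' protocols. There were 6 libraries, 1 for each of 6 groups, so each cell type had a control library, a library after 6 h of 200 nM insulin and a library after 12 h. Groups were taken from the cell type, time point and treatment labels, and the columns of the table were matched to samples through their description labels. The control is called saline in the sample titles and untreated at 0 min in the sample characteristics. The medium of all cultures was changed 4 h before treatment, to medium with 2% FBS and 5 mM glucose for astrocytes and to insulin-free serum-free medium for neurons. Time since that change therefore differed between the control and the insulin libraries.

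The authors deposited 1 table of log2 FPKM values (fragments per kilobase of transcript, scaled to library size), quantile-normalised across the 6 libraries, with gene symbols in rows. The FPKM unit, the log and the quantile step are given by the deposited table's name, and the same quantiles were found in all 6 columns. Base 2 was settled from the values. The 45S pre-rRNA gene Rn45s, 8.679 kb long in the reference table, reached 13.67, which corresponds to 113107 fragments of the unit's library total on a log2 scale. As a natural log it would be 7502196, more than that whole total. The submitters' processing notes name bcl2fastq 2.17.1.14, Partek 6.5 and the genome build Rnor 6.0. The aligner and the annotation version are not given in the sources used here. No read counts were used, so the depth of each library is unknown, and no counting interval or detection limit is given.

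The table held 37185 rows and 37183 symbols. For each of 2 repeated symbols, both of them month-like names left by a spreadsheet, the row with the higher mean was kept. A blank cell was treated as no value: 7651 symbols were blank in all libraries and 19471 had a value in every library. Of the symbols, 19872 were found among the symbols of the RefSeq table of assembly GRCr8, which was used for names and for the length of Rn45s only. No coordinates are given, because that assembly is not the build of the deposited values. The number of per-sample columns left unused was 0.

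With 1 library per group there are no replicates, and no test, standard error or p-value was computed for any comparison. A difference is the log2 value of the insulin library minus that of the control library of the same cell type, or of the astrocyte control minus the neuron control, on the deposited scale with no pseudocount. The planned size rule named log2(FPKM + 1) for linear values and the deposited scale for a table of log values. A gene entered a comparison with a value in both libraries and at least 1 FPKM in either of them. It was counted as higher or lower when its difference reached 1, a 2-fold change. "Rose" and "fell" are used of single genes only where that size was reached.

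Gene lists for lipid metabolism, glucose metabolism, mitochondria, insulin signalling, stress, inflammation, cell cycle and cell type markers were fixed before the data were examined. There were 31 lists with 506 members, of which 3 were not found. Some single genes are not reported here. Mitochondrial symbols and the stearoyl-CoA desaturase symbols were matched to the table's older names after it was seen. For each list, the median difference was taken over members at 1 FPKM or more in at least 1 of the 3 libraries of the cell type (or the 2 controls). It was placed by its percentile among 10000 random lists of the same size, matched on mean level in 20 bins. A list below the 2.5 or above the 97.5 percentile is said to lie outside the random lists, which describes these libraries and not the conditions. Lists with fewer than 5 measured members have no percentile. For random lists of unrelated genes, 4.1 of the 82 list medians of the insulin comparisons would lie outside, and 21 did. Members of a list can vary together, some lists share members, and the 2 times share a control library. The 82 medians are therefore not independent, and the excess over 4.1 is no measure of an insulin effect.

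Genes named in the text follow a rule fixed before the data were examined. For each cell type these are the 8 genes of each direction with the largest smaller difference of the 2 times, among genes moving the same way at both, and the 5 of each direction with the largest difference at each time. For the control libraries they are the 10 of each direction. All are among genes at 5 FPKM or more in at least 1 library compared. Locus identifiers and small RNA symbols were counted but not named. List members with a difference of 1 or more, the 2 to 4 largest of each list and all markers may also be named. Any gene outside this rule is said to have been chosen after its values were seen.

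The 6 h and 12 h differences of a cell type share the control library. Their correlation was set beside 100 shuffles in which each gene's 3 values were assigned at random to the 3 libraries. Such shuffles give an r near 0.50 for any data, because the 2 differences share 1 value. The alternatives tried were other pseudocounts, other floors, centring, upper-quartile scaling, leaving out small RNA and locus symbols, the mean in place of the median, another matching of random lists, and several settings added later. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedures were tested on simulated libraries with a noise SD of 0.2 and 200 changed genes. Of genes changed by 1.5 on the log2 scale, 100% were recovered for astrocyte 6 h (5856 genes), 99.0% for astrocyte 12 h (5870), 100% for neuron 6 h (6154) and neuron 12 h (6153), and 97.0% for the controls (5500). Of genes changed by 2, 100% were recovered in each, and 0 unchanged genes were called. That noise was the same at all levels and far below the cut of 1, so few false calls were possible. The real differences had SDs across genes from 0.328 (astrocyte 12 h) to 0.459 (neuron 12 h) in the insulin comparisons. The simulation therefore gives no estimate of false calls in these data. Of 200 unshifted lists of 10 genes, 4%, 5%, 7%, 3% and 6% lay outside the random lists in the same order.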

Results

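The series profiled primary rat hippocampal astrocytes and neurons before and after exposure to insulin, in connection with lipid metabolism in the brain. Each cell type had 3 libraries, a control at 0 h and cultures after 6 h and 12 h of 200 nM insulin, with 1 library per group and therefore no replicates. Between 5781 and 6447 symbols per library were at 1 FPKM or more, and between 1742 and 1943 were at 5 FPKM or more. The 3 most abundant symbols held 60.1% of the summed FPKM in the astrocyte control and 57.2% in the neuron library at 12 h. As all libraries were given the same quantiles, these counts and shares follow the number of symbols with a value. That number was 22891, 23814 and 23898 in the astrocyte control, 6 h and 12 h libraries. In the neuron libraries it was 23927, 25510 and 25528. Across 7754 genes with a value in all libraries and at least 1 FPKM in 1 of them, Pearson's r was 0.985 between the astrocyte control and its 6 h library, and 0.478 between the astrocyte and neuron controls. These correlations are across genes, which are not independent replicates.

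The control libraries of the cell types were compared first, since they show which cells the labels describe. The library labelled neuron carried neuronal transcripts together with glial ones. Gad1, which makes GABA, was at 5.78 FPKM in the neuron control and Tubb3, a neuronal tubulin, at 30.0 FPKM, against 0.532 FPKM of Tubb3 in the astrocyte control. All 11 neuron markers with a value in both controls were higher in the neuron control, and 2 were blank in the astrocyte control, with a median difference of -5.81 over the 9 that reached 1 FPKM. Of 11 astrocyte markers with a value in both, 10 were also higher in the library labelled neuron, and 1 more was blank in the astrocyte control. The intermediate filament gene Gfap was at 96.7 FPKM there and 6.23 FPKM in the library labelled astrocyte, the water channel gene Aqp4 at 26.6 against 0.0985 FPKM, and glutamine synthetase (Glul) at 106 against 5.32 FPKM. Fgfr3 was the exception, at 22.1 FPKM in the astrocyte control and 3.70 FPKM in the neuron control. Of 6 oligodendrocyte markers 5, and of 5 precursor markers 4, with a value in both were higher in the library labelled neuron, with Olig1 at 80.6 FPKM. Olig2 was at 25.9 FPKM there and blank in the astrocyte control. The exceptions were Mog, at 2.21 FPKM in the astrocyte control and 1.69 FPKM in the neuron control, and Cspg4, at 1.32 and 0.397 FPKM. The excitatory marker Slc17a7 was at 0.00241 FPKM there.

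The library labelled astrocyte carried abundant transcripts of contractile and matrix-producing cells. Smooth muscle actin (Acta2) was at 54.4 FPKM, Tagln at 353 FPKM, the collagen genes Col1a1 and Col3a1 at 44.2 and 21.4 FPKM, and fibronectin (Fn1) at 28.2 FPKM. In the neuron control Tagln was at 4.35 FPKM and the other 4 were below 0.1 FPKM. All 5 pericyte and smooth muscle markers and all 4 fibroblast markers with a value in both were higher in the library labelled astrocyte, and 1 and 2 more were blank in the neuron control. The 10 named genes of largest excess there were Col3a1, Acta2, Lox, S100a6, Car9, Cnn1, Col1a1, Tpm2, Ankrd1 and Ltbp2, with log2 differences from 11.54 to 14.79. The 10 of largest excess in the neuron control were Gad1, Olig1, Stmn3, Mapk8ip2, Dcx, Adcyap1r1, Pcdh8, Bcan, Kcna2 and Ednrb, with differences from -12.71 to -10.54. In the control where they were lower, these genes were at 0.0409 FPKM or less, so the sizes and their order are uncertain. Genes blank in 1 control were not ranked. Of genes at 1 FPKM or more, 42 in the astrocyte control were blank in the neuron control, and 77 the other way. Microglia and endothelial markers were below 1 FPKM in both controls. The ependymal marker Foxj1 was at 1.34 FPKM in the neuron control and 0.0278 FPKM in the astrocyte control. Because of these levels, the libraries are called astrocyte-labelled and neuron-labelled here.

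**Figure D1:**
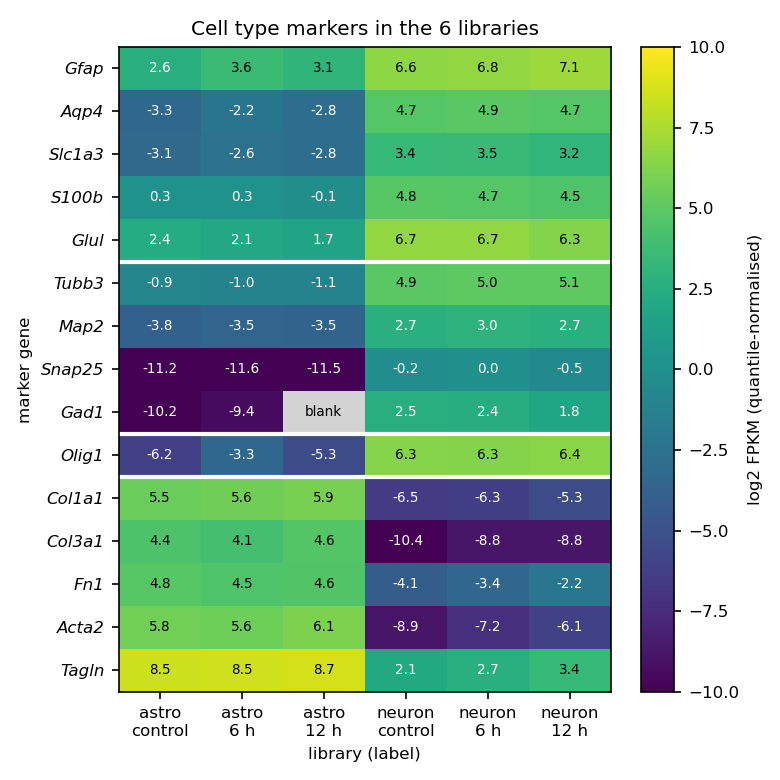
Log2 FPKM (quantile-normalised) of 15 marker genes in the 6 libraries, as deposited, with the value written in each cell and grey for a blank. Rows run from astrocyte markers to neuron markers, Olig1 and genes of fibroblasts and mural cells, and Gfap was 6.60 in the neuron control against 2.64 in the astrocyte control.

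Of 7146 genes in this comparison, 1337 were at least 2-fold higher in the astrocyte-labelled control and 1565 in the neuron-labelled control. Cell cycle genes were higher in the astrocyte-labelled control, with 16 of 19 measured members at least 2-fold higher, a median of 2.62 and a place above all 10000 random lists. Inflammatory genes (median 2.05, percentile 99.7), cholesterol synthesis genes (0.57, percentile 98.5) and cytosolic ribosomal protein genes (0.60, percentile 99.7) were also above the random lists. Of the other lipid lists, 2 were below the random lists. Fatty acid synthesis and desaturation genes had a median of -1.61 (percentile 0.18), with Srebf1 at 1.48 FPKM in the astrocyte-labelled control and 44.0 FPKM in the neuron-labelled control. Fatty acid uptake and lipoprotein genes had a median of -1.02 (percentile 0.25), and Apoe was at 5.15 FPKM against 745 FPKM. The 13 mitochondrially encoded genes (-1.77, below all random lists), nuclear-encoded respiratory chain genes (-0.76, percentile 0.25), pyruvate dehydrogenase and TCA cycle genes (-0.60, percentile 2.12) and stress response genes (-1.26, below all random lists) were lower as well. Synaptic genes (-4.51, percentile 2.10), astrocyte markers (-3.96, below all random lists), neuron markers (percentile 0.02) and oligodendrocyte markers (-5.46, percentile 0.865) completed the lists outside the random ones. Mitochondrial beta-oxidation genes had a median of -0.28 (percentile 37.7). The remaining lists with 5 or more members lay inside, with percentiles from 2.99 to 95.8.

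The next comparison asked what changed in the astrocyte-labelled cultures after insulin. Cholesterol synthesis genes were higher at both times, the 5 measured of 20 FoxO and fasting-response genes were lower, and most transcripts of the mitochondrial genome were lower. The median of all genes was 0.09 at 6 h and 0.10 at 12 h, and part of each list median is this shift. The control had 22891 symbols with a value, against 23814 at 6 h and 23898 at 12 h. Under shared quantiles, more symbols with a value put a gene of the same rank from the top higher. The shift is therefore no measure of insulin raising most genes. Between the 12 h and 6 h libraries the median was 0.019. Of 20 measured cholesterol genes and SREBP2 targets, 19 were above the all-gene median at 6 h and 20 at 12 h. Their median was 0.29 at 6 h (0.20 above all genes, percentile 99.8) and 0.49 at 12 h (0.39 above, higher than all random lists). None reached 2-fold. Lss, lanosterol synthase, was at 0.606, 0.827 and 1.11 FPKM in the control, 6 h and 12 h libraries.

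Fatty acid synthesis and desaturation genes had a median of 0.23 at 6 h, inside the random lists (percentile 93.2), and 0.33 at 12 h (0.23 above all genes), above them (percentile 99.6). Stearoyl-CoA desaturase 1 (Scd1) rose by 1.15 at 12 h, from 0.832 to 1.84 FPKM, and fatty acid synthase (Fasn) was at 6.78, 8.58 and 9.15 FPKM. Mitochondrial beta-oxidation genes, which the study's title brings into question, had medians of 0.23 at 6 h (percentile 87.2) and 0.11 at 12 h (percentile 45.4) over 9 measured members, and none reached 2-fold. With no floor the 6 h median was 0.0871, and centred on the genes at 5 FPKM or more the 12 h median was 0.0258. The largest member difference was 0.62 for Cpt1c at 12 h, at 1.02 FPKM in the control and 1.57 FPKM at 12 h. Acadvl, which opens the oxidation of long chains, was at 4.77, 5.79 and 6.09 FPKM. The droplet and lipolysis list lay inside the random lists at both times (percentiles 92.8 and 81.4). Within it G0s2, an inhibitor of the lipase Pnpla2, rose at both times, by 2.27 at 6 h, and was at 0.471, 2.28 and 1.33 FPKM. Uptake and lipoprotein genes lay inside at both times (percentiles 92.5 and 13.8).

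All 5 measured FoxO and fasting-response genes were lower at both times, with medians of -0.54 at 6 h (-0.64 from all genes, below all random lists) and -0.36 at 12 h (-0.46 from all genes, percentile 0.095). None reached 2-fold, and whether FoxO factors were involved was not tested. Without members that other lists also hold, a setting chosen after seeing the data, too few were left for a percentile. Irs2, an insulin receptor substrate, was at 2.63 FPKM in the control, 1.80 at 6 h and 1.76 at 12 h, and Txnip, which restrains glucose uptake, was at 15.9, 10.3 and 12.4 FPKM. Glycolysis and glucose uptake genes had medians of 0.27 at 6 h (0.18 above all genes, percentile 99.3) and 0.24 at 12 h (0.13 above, just past the upper limit, and 0.15 when centred), with Ldha at 15.6, 22.5 and 22.2 FPKM. Without members that other lists also hold, a setting chosen after seeing the data, the glycolysis medians were 0.25 (percentile 96.7) and 0.21 (percentile 91.6), inside the random lists. Tpi1, a glycolytic enzyme, rose by 2.11 and 2.18, from 1.65 FPKM. Inflammatory genes were higher at 6 h (median 0.61, or 0.51 above all genes, above all random lists, and 0.37 with log2(FPKM + 1), chosen after seeing the data) and not at 12 h (0.01, percentile 22.6). The chemokine genes Ccl2 and Ccl7 rose by 1.48 and 1.56 at 6 h, to 12.0 and 9.79 FPKM, and were at 5.18 and 3.65 FPKM at 12 h. Hypoxia-response genes were above the random lists at 6 h (0.34, or 0.25 above all genes, percentile 99.2) but not when members of other lists were left out (0.21, percentile 83.8, also chosen after seeing the data). At 12 h their percentile was 93.8. Immediate-early genes were inside at 6 h (percentile 30.8) and below the random lists at 12 h (-0.22, or -0.33 from all genes, percentile 0.02), where Egr1 fell by 1.16. Fosl1 of that list rose by 1.16 at 6 h.

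The 13 mitochondrially encoded genes had medians of -0.99 at 6 h and -0.36 at 12 h (-1.08 and -0.47 from all genes), below all random lists at each time. At 6 h, 5 of them fell, ND5 by 1.31, from 108 to 43.5 FPKM. Nuclear-encoded respiratory chain genes did not move with them (medians 0.11 and 0.13, percentiles 64.2 and 71.9). The other lists with 5 or more members lay inside the random lists at both times, with percentiles from 4.29 to 96.7. They were the pyruvate dehydrogenase and TCA cycle, insulin signalling, stress response, cell cycle, heat-shock, astrocyte marker and cytosolic ribosomal protein lists. Under matching on all 6 libraries the 12 h stress response list was above the random lists, at percentile 98.5. Another 12 lists had fewer than 5 measured members and no percentile: peroxisomal oxidation, ketone bodies and monocarboxylate transport, synaptic genes, interferon-stimulated genes and 8 lists of markers of other cells.

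In all, 65 genes were higher and 55 lower at 6 h of 6206 compared, and 38 were higher and 57 lower at 12 h of 6221. Locus identifiers and small RNA symbols made up 26 of the 65 and 30 of the 55 at 6 h, and 15 of the 38 and 33 of the 57 at 12 h. The 12 h library differed from the 6 h library by 16 genes higher and 32 lower. The 8 named genes above 0 at both times with the largest smaller difference were Tpi1, Dpm3, Igfbp3, Gas5, Fv1, Tubb2a_1, Hsc70-ps1 and Rmrp, of which Tpi1 and Dpm3 reached 2-fold at both. Fv1 (0.87 and 0.95) and Hsc70-ps1 (0.80 and 0.83) reached it at neither time, and Tubb2a_1 only at 6 h. Igfbp3, a carrier of insulin-like growth factors, rose by 1.46 at 6 h, from 3.77 to 10.4 FPKM, and was at 7.31 FPKM at 12 h. Gas5, a noncoding host of small nucleolar RNAs, was at 8.33, 15.4 and 19.7 FPKM, and rose by 1.24 at 12 h. Rmrp, the RNA of RNase MRP, rose at 6 h, from 4569 to 12927 FPKM, and was at 7785 FPKM at 12 h. The splicing factor rows Srsf5_1 and Srsf5_2 rose by 1.04 and 1.55 at 12 h. The 8 below 0 at both times by the same rule were Rps6, Dpm3-ps1, Rn18s, Rpl38-ps2, Rps9, Rpl41-ps1, ND5 and Timp1. Rps9 (-0.94) and ND5 (-0.63) fell short of 2-fold at 12 h, and Rpl41-ps1 (-0.79) at 6 h. The metalloproteinase inhibitor gene Timp1 differed by -0.60 and -0.65, short of it at both times, and the 18S rRNA gene Rn18s by -2.01 and -1.21. Tpi1, Rps6, Rps9, Dpm3, Tubb2a_1, the Srsf5 rows and the rows ending in ps have near-identical copies or pseudogenes, so their values are uncertain.

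Centring on the median of genes at 5 FPKM or more turned the counts into 45 higher and 62 lower at 6 h and 30 higher and 68 lower at 12 h. The control was taken at 0 h, so the insulin effect is not separated from time in the changed medium.

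**Figure D2:**
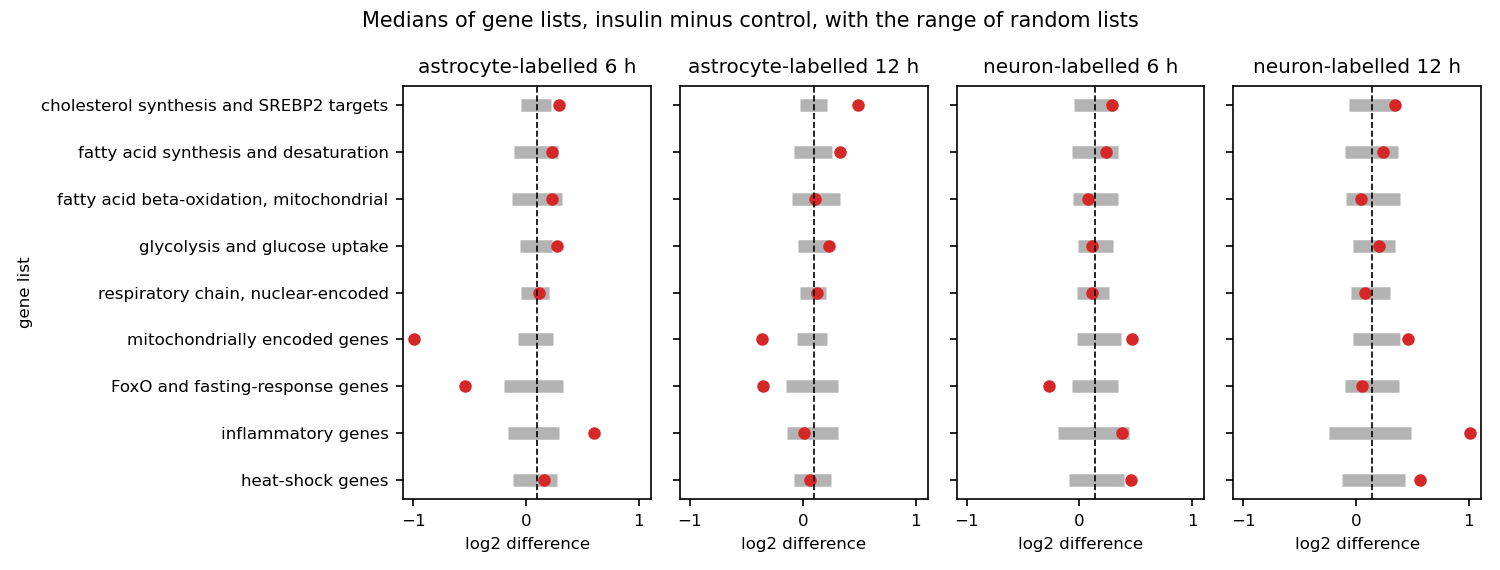
Medians of 9 gene lists (red points, log2 difference between insulin and control) in the 4 comparisons, with grey bars for the central 95% of 10000 random lists and a dashed line for the median of all genes. The mitochondrially encoded genes lie at -0.99 in the astrocyte-labelled 6 h library and at 0.47 in the neuron-labelled 6 h library.

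The same comparison was made in the neuron-labelled cultures. The median of FoxO and fasting-response genes was below the random lists at 6 h, those of heat-shock and mitochondrially encoded genes were above them at both times, and at 12 h that of inflammatory genes was above and that of neuron markers below. The median of all genes was 0.14 at 6 h and 0.14 at 12 h. Here too the insulin libraries had more symbols with a value (25510 and 25528, against 23927 in the control), which lifts this median. Between the 12 h and 6 h libraries it was -0.007. The FoxO list had a median of -0.27 at 6 h (0.41 below all genes on the log2 scale, percentile 0.01), with a mean of -0.12, 7 members below 0 and 4 above, and a median of 0.05 at 12 h (percentile 26.5). In settings chosen after seeing the data the 6 h median was -0.17 without members that another list holds (percentile 0.18) and -0.18 with log2(FPKM + 1). Pik3ip1, an inhibitor of PI3 kinase, was at 1.48, 0.997 and 1.13 FPKM, and Txnip was at 14.4, 10.6 and 18.9 FPKM. Cholesterol genes had medians of 0.29 at 6 h, inside the random lists (percentile 96.2), and 0.35 at 12 h (0.20 above all genes), above them (percentile 97.9). Under matching on all 6 libraries the 12 h list was inside, at percentile 95.4. Idi1, isopentenyl-diphosphate isomerase, rose by 1.01 at 6 h and differed by 0.90 at 12 h, at 3.66, 7.36 and 6.84 FPKM.

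Mitochondrial beta-oxidation genes had medians of 0.07 at 6 h (percentile 27.7) and 0.04 at 12 h (percentile 20.8) over 10 measured members, below the median of all genes, and none reached 2-fold. Centred on the genes at 5 FPKM or more, these medians were -0.04 and -0.07. Fatty acid synthesis genes (percentiles 85.6 and 79.7), peroxisomal oxidation genes (52.9 and 44.4), uptake genes (18.4 and 34.4) and droplet genes (22.4 and 46.3) were inside the random lists. The lipase gene Pnpla2 fell by 1.46 at 6 h, from 2.30 to 0.834 FPKM, and was at 1.45 FPKM at 12 h. Glycolysis genes were inside as well (percentiles 34.5 and 71.2).

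Heat-shock genes had medians of 0.46 at 6 h (0.32 above all genes, percentile 99.2) and 0.57 at 12 h (0.42 above, percentile 99.8). Hspa1b, an inducible HSP70 gene with a near-identical copy, rose by 1.22 and 1.68, from 1.72 to 4.01 and 5.53 FPKM, and the chaperonin gene Hspd1 was at 8.53, 11.7 and 12.6 FPKM. Inflammatory genes had a median of 0.37 at 6 h (percentile 94.5) and 1.01 at 12 h (0.87 above all genes), above all random lists, with 3 of 5 members at least 2-fold higher at 12 h. Ccl2 rose by 1.52 and 2.58, from 1.05 FPKM to 6.26 FPKM at 12 h, Cxcl1 rose by 1.20 and 1.22, and the adhesion gene Icam1 rose by 1.01 at 12 h. Microglia markers other than Cx3cr1 were higher at 12 h than in the control, but all stayed below 1 FPKM. C1qa was at 0.181, 0.275 and 0.498 FPKM, and Aif1 at 0.00463, 0.0308 and 0.0846 FPKM.

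Neuron markers were inside the random lists at 6 h (percentile 32.6) and below them at 12 h, with a median of -0.32 (-0.46 from all genes, percentile 0.08), or -0.20 with log2(FPKM + 1), chosen after seeing the data. Nefl, a neurofilament gene, was at 14.7, 13.7 and 7.33 FPKM, Gad1 at 5.78, 5.38 and 3.38 FPKM, and Tubb3 at 30.0, 32.5 and 33.7 FPKM. Astrocyte markers were also below the random lists at 12 h (-0.18, or -0.32 from all genes and -0.29 when centred, percentile 1.76) and inside at 6 h (percentile 22.1). Without Aldoc, the 1 member that another list also holds, the 12 h median was -0.09 (percentile 5.72), a setting chosen after seeing the data. Glul was at 106, 106 and 77.7 FPKM, while Gfap was at 96.7, 109 and 134 FPKM. Synaptic genes had percentiles of 18.3 and 4.73 and oligodendrocyte markers of 6.08 and 5.06.

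The 13 mitochondrially encoded genes had medians of 0.47 at 6 h (0.33 above all genes, percentile 99.9) and 0.46 at 12 h (0.32 above, percentile 99.6). COX1 rose by 1.71 and 1.13. Nuclear-encoded respiratory chain genes had medians of 0.11 and 0.08 (percentiles 42.9 and 32.8). The one member of that list that rose was Cycs, cytochrome c, which has many pseudogenes and went from 8.57 to 29.5 and 25.5 FPKM. The pyruvate dehydrogenase and TCA cycle, insulin signalling, immediate-early, stress response, hypoxia-response and cytosolic ribosomal protein lists were inside the random lists at both times (percentiles from 11.7 to 94.4). The 9 lists with fewer than 5 measured members were ketone bodies and monocarboxylate transport, cell cycle, interferon-stimulated genes and 6 lists of markers of other cells.

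In the neuron-labelled libraries 106 genes were higher and 85 lower at 6 h of 6610 compared, and 159 were higher and 96 lower at 12 h of 6641. Locus identifiers and small RNA symbols made up 58 of the 106 and 60 of the 85 at 6 h, and 76 of the 159 and 54 of the 96 at 12 h. The 8 named by this rule among genes higher at both times were Vma21, Cycs, Rmrp, Ccl2, Dpm3, Rnf11l2 and the rows Trna and Trng. The symbols Trna and Trng have the form of mitochondrial tRNA gene names, and the processing counted such symbols as mitochondrial. They were not found in the reference table, so their identity was not checked. Vma21, an assembly factor of the vacuolar proton pump, rose by 1.72 and 1.65, from 1.59 FPKM, and Rmrp rose by 1.54 at each time. Tubb6, a tubulin gene, differed by 0.89 at 6 h and rose by 1.77 at 12 h, at 3.54, 6.58 and 12.1 FPKM. Those among genes lower at both times were Rn18s, Dll4, Rn5-8s, Rn28s, Dolpp1, Arhgef40, Hist2h4 and Rpl35a. The 18S rRNA gene Rn18s differed by -4.45 and -5.65, from 234 FPKM, and Rn28s by -3.05 and -3.65. Dll4, which encodes a Notch ligand, differed by -3.42 and -4.35, from 5.75 FPKM, and Dolpp1 by -1.84 and -1.60, from 109 FPKM. Grcc10 fell by 1.74 at 12 h. The rows Rnf11l2, Cycs, Dpm3, Hist2h4 and Rpl35a have close copies in the genome and are uncertain.

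Centring turned the neuron counts into 76 higher and 105 lower at 6 h and 119 higher and 122 lower at 12 h. The 12 h library differed from the 6 h library, without the control, by 37 genes higher and 34 lower of 6662. The control library of these cells held the most Rn18s of the 6 libraries, with a log2 value of 7.87 against 3.70 in the astrocyte control, the next highest.

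**Figure D3:**
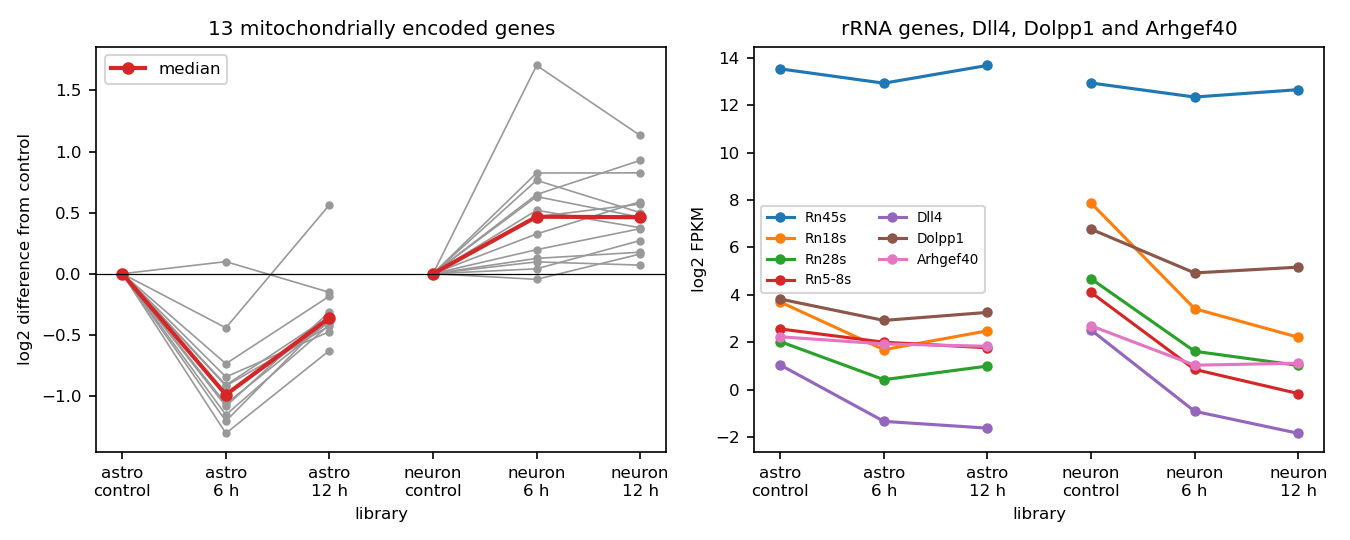
Left, log2 difference from the control of the same cell type for each of the 13 mitochondrially encoded genes (grey) and their median (red) by library. Right, log2 FPKM of rRNA genes and of Dll4, Dolpp1 and Arhgef40 by library, where Rn18s goes from 7.87 in the neuron control to 2.22 at 12 h and Rn45s from 12.93 to 12.65.

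The responses of the cell types were compared across the 4382 genes at 1 FPKM or more in all 6 libraries. Pearson's r was 0.0570 at 6 h and 0.182 at 12 h, and Spearman's rho was -0.129 and 0.105. These correlations are across genes and the differences compared share no library. At 6 h, 3 genes rose and 7 fell in both cell types, against 0.169 and 0.199 for independent lists. The 3 were Ccl2, Dpm3 and Rmrp, and the 7 were Rn18s, Rn28s and 5 locus symbols. At 12 h, 1 gene (Dpm3) rose and 6 fell in both, again Rn18s, Rn28s and locus symbols. Without mitochondrial, rRNA and locus symbols, a setting chosen after seeing the data, 0 genes fell in both at either time and r at 6 h was -0.0613. With a floor of 5 FPKM in all libraries it was 0.149. The difference in response between the cell types was not tested, for lack of replicates.

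The 6 h and 12 h differences were alike within each cell type, but they share a control library. In the astrocyte-labelled libraries r was 0.655 across 6360 genes against 0.50 in shuffled data, with a covariance of 0.0739 against 0.0531. In the neuron-labelled libraries r was 0.809 across 6771 genes against 0.50 in shuffled data, with a covariance of 0.152 against 0.0817. At both times 20 genes were higher and 28 lower in the astrocyte-labelled libraries, against 0.399 and 0.484 for independent lists and 13.8 and 13.9 in shuffled data. For the neuron-labelled libraries 80 were higher and 54 lower, against 2.71 and 1.15 for independent lists and 34.3 and 27.9 in shuffled data. With a single control library, which cannot be split, the part of the excess that comes from the shared control is not known.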

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

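The tests of the normalization were written before their results were seen, and the others were chosen after.

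The median of the 13 mitochondrially encoded genes went in opposite directions in the cell types, a difference that was not tested for lack of replicates. The median log2 difference was -0.99 at 6 h and -0.36 at 12 h in the astrocyte-labelled libraries, and 0.47 and 0.46 in the neuron-labelled ones, with 12 genes below 0 at each time in the former and 12 and 13 above 0 in the latter. Genes within 0.5 log2 of them in the control had a median difference of 0.0762 in the astrocyte-labelled library nearer to the pattern. In the neuron-labelled library nearer to it the median was 0.16. For the most abundant, as few as 1 or 2 genes lay that close. The same quantiles in all libraries hold such medians near the shift of all genes. They therefore cannot decide whether quantile normalization made the pattern. A joint change of both genomes is argued against by the nuclear-encoded respiratory chain list, which lay inside the random lists in 4 of 4 comparisons. The astrocyte-labelled 12 h library was above the 6 h library by a median of 0.63, with 12 of 13 genes higher, a gap that the control does not enter. With 1 library per group, an odd astrocyte control together with variation between libraries cannot be told apart from an effect of insulin or of time. In the neuron-labelled libraries that median was 0.0508, so an odd neuron control and such an effect cannot be told apart there either.

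The locus LOC103690015 was the only one of 4382 genes past 2-fold in opposite directions in all 4 comparisons, again without a test. It differed by 2.15 and 2.496 at 6 h and 12 h in the astrocyte-labelled libraries and by -1.61 and -1.71 in the neuron-labelled ones.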

How the results depend on the processing

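The 2-fold counts depended on the floor, the pseudocount and the treatment of unnamed symbols, by construction, since each sets how many low or unnamed genes can pass. Counts are given as higher and lower, in the order astrocyte 6 h, astrocyte 12 h, neuron 6 h, neuron 12 h and the controls. With a floor of 5 FPKM they were 14 and 21, 8 and 13, 26 and 37, 39 and 36, and 445 and 532. With no floor they were 1961 and 912, 1939 and 931, 3049 and 875, 3252 and 947, and 4454 and 5248. Without small RNA and locus symbols the insulin counts were 39 and 25, 23 and 24, 48 and 25, and 83 and 42. With log2(FPKM + 0.1) astrocyte 6 h had 43 higher and 49 lower, so more genes were lower than higher. Upper-quartile scaling gave 42 and 64, 29 and 71, 69 and 107, and 106 and 139 for the insulin comparisons, which turned the split from mostly higher to mostly lower in astrocyte 6 h, neuron 6 h and neuron 12 h.

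Other settings were added as alternatives after seeing the data. One was log2(FPKM + 1), which the size rule had named for a table of linear values. With it the counts were 14 and 21, 8 and 19, 28 and 37, 35 and 32, and 838 and 984. This turned the split from mostly higher to mostly lower in astrocyte 6 h and neuron 6 h. With the 6 h insulin library in place of the control the 12 h counts were 16 and 32 for astrocytes and 37 and 34 for neurons.

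The astrocyte 6 h beta-oxidation median was 0.0871 with no floor. The neuron medians at 6 h and 12 h were -0.0377 and -0.0722 when centred and -0.0701 and -0.11 under upper-quartile scaling. These lists lay inside the random lists under each alternative with 5 or more members, which a floor of 5 FPKM did not leave. Their place still moved with no floor. The percentiles at 6 h and 12 h were then 29.75 and 26.16 for astrocytes, against 87.22 and 45.43. For neurons they were 5.90 and 5.39, against 27.72 and 20.77. Of the 21 list medians outside the random lists, 21 stayed outside with log2(FPKM + 0.1) and 20 with matching on all 6 libraries, where the neuron 12 h cholesterol list, median 0.35, moved inside and the astrocyte 12 h stress response list, median 0.22, moved outside. Centring shifts a list and its random lists alike and cannot move a percentile. Of the settings chosen after seeing the data, log2(FPKM + 1) kept 20, with the astrocyte 6 h hypoxia median at 0.20 and inside, and added the astrocyte 12 h stress response (0.19) and neuron 6 h cholesterol (0.22) lists. Leaving out members of more than 1 list kept 15, with astrocyte glycolysis at 0.25 and 0.21, astrocyte 6 h hypoxia at 0.21 and neuron 12 h astrocyte markers at -0.0943 inside and too few members left of the astrocyte FoxO list at both times. Leaving out Scd1 kept 21. Pearson's r between the cell types at 6 h turned to -0.0613 without mitochondrial, rRNA and locus symbols, a setting chosen after seeing the data, and the cause was not tested. The depth is unknown, so low values carry an error that cannot be given. No paired analysis was possible because the labels give no replicate or culture that libraries share. A fit with cell type as a block was not run, since its residual would hold the difference in response between the cell types.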

Other observations

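The genes in this paragraph were chosen after their values were seen, and none is part of a list fixed beforehand except where marked. In the neuron-labelled 12 h library Sst, Npy, Cort and Scg2 fell. Sst, somatostatin, was at 154, 122 and 48.5 FPKM in the control, 6 h and 12 h libraries, Npy was at 2.40, 1.74 and 0.358 FPKM, Cort at 4.77, 3.67 and 0.972 FPKM, and Scg2 at 34.2, 35.0 and 15.2 FPKM. Of 3 other peptide genes, Penk was at 5.53, 5.03 and 3.22 FPKM, Cck at 3.84, 4.08 and 4.14 FPKM and Vip at 0.528, 0.767 and 0.845 FPKM. Flnc, Nes and Cd44 rose in the same library. Flnc, a filamin, was at 0.377, 0.733 and 1.93 FPKM, Nes, nestin, at 14.4, 20.3 and 35.5 FPKM, and Cd44 at 0.632, 1.08 and 1.68 FPKM. Vim, vimentin, was at 23.5, 26.2 and 46.6 FPKM, short of 2-fold, and beta-actin (Actb) differed by 0.0957 at 12 h. Tagln, from the mural marker list, was at 4.35, 6.53 and 10.3 FPKM. Col1a1, from the fibroblast list, was at 0.0113, 0.0131 and 0.0246 FPKM, a difference of 1.12 at 12 h but at levels far below 1 FPKM.

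In the astrocyte-labelled libraries, 2 genes rose at 6 h and were near or below the control at 12 h, also chosen after their values were seen. Igfbp5, a carrier of insulin-like growth factors, was at 1.76, 3.70 and 1.91 FPKM, and Mgp, matrix Gla protein, was at 0.481, 1.02 and 0.315 FPKM.

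All tests in the next 2 paragraphs were chosen after the result was seen, except that of the normalization. In the neuron-labelled insulin libraries the rRNA genes Rn18s, Rn28s and Rn5-8s fell together with Dll4, Dolpp1 and Arhgef40. Genes at a like level in the control had a median difference of 0.10 at 6 h and 0.0863 at 12 h, so the named genes fell relative to them. The same quantiles in all libraries hold such a median near the shift of all genes. It therefore cannot decide whether normalization set the size of the fall. More residual rRNA in the neuron control would lower the 45S gene Rn45s as well, which differed by -0.59 at 6 h and -0.28 at 12 h. Rn45s is 1 gene at rank 5, 7 and 6 of the quantile-normalised libraries, where a few ranks set its value, so more residual rRNA and an effect of insulin or time cannot be told apart. A candidate explanation for Dll4, Dolpp1 and Arhgef40 is that reads of ribosomal origin were counted under them. All 3 were lower in the astrocyte-labelled insulin libraries too, in 6 of 6 cases, where Rn18s and Rn28s also fell. Hist2h4 (-0.11 and -0.58) and Rpl35a (-0.48 and -0.44), not rRNA genes, were lower in those libraries as well. From 6 h to 12 h, Rn18s (-2.01 to -1.21) and Dolpp1 (-0.90 to -0.56) moved towards the control. Dll4 (-2.37 to -2.66) and Arhgef40 (-0.30 to -0.40) moved away from it. The shared direction therefore cannot decide whether ribosomal reads were counted under these genes.

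The markers of the cultures raise a question about which cells they held. A swap of the cell type labels is argued against by the neuron markers, of which 0 of 13 were higher in the astrocyte-labelled control, where 2 were blank. The neuron-labelled cultures may hold many astrocytes, with 9 of 12 astrocyte markers at 1 FPKM or more in their control. In the astrocyte-labelled control 7 of 12 reached that level, so this count hardly separates the cultures. Of the 11 with a value in both controls, 10 were higher in the neuron-labelled one. In the astrocyte-labelled cultures, 12 of 12 fibroblast and mural markers found were higher than in the neuron-labelled control when the 3 blank there are counted as lower, and fibroblast, meningeal or mural cells cannot be told apart from astrocytes changed by growth in serum, which also make several of these transcripts. No library of cells sorted by type was analysed here.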
